A study of Mus musculus with 3 samples.

How the data were processed

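The series describes 3 samples of MA-10 cells, a mouse Leydig cell tumour line: a library titled B2-AS, a wild-type library and a library from cells with Dicer1 knockdown. Each group held 1 sample. The submitters' processing notes name Bowtie 0.12.2 and the mm9 genome build. The table analysed here lists exon intervals with a transcript name, chromosome, start, end and strand, and 2 columns of per-sample values. The name the authors gave the table describes these values as a base pair quantitation, and the negative, non-integer values in it are not raw counts and appear to be on a log scale. The base of that scale, the scaling between libraries and any further step are not given in the sources used here. The names of those 2 columns matched no label of any sample, so neither could be assigned to the wild-type or the knockdown library without guessing, and neither was used. The annotation columns were summarised with Python 3.11.15 and pandas 2.3.3. The planned comparison of Dicer1 knockdown with wild type, its gene lists and its alternatives were therefore not run. The B2-AS library was not analysed here.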

Results

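The transcriptomes of wild-type MA-10 cells and of MA-10 cells with knockdown of Dicer1, the ribonuclease that cuts double-stranded RNA and microRNA precursors, were to be compared, with 1 library in each group. The table analysed here held 336032 distinct exon intervals under 83475 transcript names on 22 chromosome names, with a median length of 144 bases. Of these intervals, 169264 lay on the plus strand and 166768 on the minus strand. Each interval was listed only 1 time, so an exon shared with identical bounds by several transcripts appeared under 1 name. The names, counts and spans given below therefore describe this listing and need not match the full exon structure of the transcripts. Dicer1 was represented on chromosome 12, minus strand, by 4 transcript names. One of them had 10 intervals between positions 105925952 and 105958879, and another had 11 between 105930337 and 105969392. The other 2 had 4 intervals between 105960294 and 105977047 and 6 between 105946986 and 105990162. Tspo, which encodes the translocator protein of the outer mitochondrial membrane, was represented by 1 transcript name with 4 intervals between positions 83394003 and 83404631 on the plus strand of chromosome 15. Positions are as the table gives them, and the submitters' processing notes name the mm9 build.

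No expression level, depth or difference between the wild-type and knockdown libraries is reported, because the 2 columns of values could not be assigned to these libraries from the labels.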

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

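None of the alternatives planned before the data were examined was run. Each needs the library values that could not be assigned: other scalings, pseudocounts, minimum levels and ways of joining the intervals of a gene, for the Dicer1 ratio, the counts of genes and the gene lists. The alternatives for the SINE B2 result needed transcript sequences as well, which were not used here. The only choices recomputed were added after seeing the data and concern the listed exon intervals. Merging intervals that share at least 1 base on the same strand left 230871 of 336032, and merging without regard to strand left 226639. The median length was 144 bases as listed and 147 bases after either merging. No comparison between groups, paired or unpaired, was made, because the library values could not be assigned. With 1 sample in each group, a paired analysis would not have been possible in any case.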
